A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

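Total RNA of 6 shake-flask cultures of the Saccharomyces cerevisiae strain CEN.PK113-7D was measured on Affymetrix yeast expression arrays, 1 array per culture, 3 with BSA and 3 without. Per the labels' protocols, cultures were grown in baffled flasks at constant temperature with shaking, RNA was purified with an RNeasy kit, and biotin-labelled cRNA was prepared with a 3' amplification kit. The deposited values are log2 expression values per probe set, made by the authors with PLIER and R 2.10.1, per the submitters' processing notes. The part each of these programs played, the background correction, the normalization between arrays and any filter on probe sets are not given in the sources used here. The base of the logarithm is not stated either, and base 2 was taken from the range of the deposited values. An annotation table deposited with the series pairs each probe set with a systematic ORF name. Gene names and gene lengths, which can include introns, were taken from the reference gene table of the S. cerevisiae genome assembly R64.

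Each array was assigned to its group from the labels. The deposited table held 5705 probe sets. Where several probe sets measured 1 gene, the probe set with the highest mean over the 6 arrays was kept, which left 5657 genes. Of these, 117 were read by probe sets whose type marks a possible shared signal with other genes. The values were used as deposited, without further normalization. No sequencing depth applies to arrays, and precision is given by SDs between replicate arrays and by SEs of the fits.

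The comparison of BSA with no BSA was fitted gene by gene in R 4.3.3 with limma 3.58.1 (moderated t-test). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. For 40 gene lists written before the data were examined, the 39 with at least 5 measured genes were tested with camera of the limma package with a preset correlation between genes of 0.01, again with a Benjamini-Hochberg adjusted p under 0.05, and the test was repeated with an estimated correlation. Counts of list members called over all genes are given beside counts with p adjusted over the list alone. The lists covered cytoplasmic and mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, nitrogen catabolite repression, proteases, amino acid and peptide transport, amino acid biosynthesis, sulfur, iron, zinc, copper and phosphate. Further lists covered glycolysis, hexose transport, gluconeogenesis, the TCA cycle, respiration, beta-oxidation, fatty acids and phospholipids, ergosterol, hypoxic genes, general and oxidative stress, chaperones, ER folding, secretion, glycosylation and the cell wall. The remaining lists held genes of trehalose and glycogen, autophagy, histones and replication, the proteasome, vitamins, purines, multidrug resistance, a-cells, alpha-cells, the pheromone response and meiosis.

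Genes named in the text followed a rule fixed before the data were examined. It took the 12 genes with the highest and the 12 with the lowest log2 fold change among called genes whose groups did not overlap, and up to 4 members with the smallest p of each list past the threshold and of 6 lists on nitrogen, proteases, transport, amino acid biosynthesis, ER folding and secretion. It also took the genes of small counts, and genes chosen otherwise are said to be so.

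Alternatives planned before the data were examined were the replicate number as a block, an intensity trend in the variance prior, a robust prior, array weights, a plain t-test, quantile normalization, centring each array on its median, leaving out the dimmest 25% or the dimmer 50% of genes, the mean of all probe sets of a gene, every probe set kept, leaving out each array in turn, an adjusted p under 0.01 and a change of at least 2-fold. For lists, camera with an estimated correlation, camera on ranks and fry were planned as well. Added after the data were seen were control replicates 2 and 3 counted as 1 sample, centring each array on the median of its deviations from the gene means, cyclic loess normalization, and leaving out probe sets that can share signal. The 4 scalings meant in the text are quantile normalization, both kinds of centring and cyclic loess.

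The fit was tested on simulated data with the means and variances of the real genes. Of 50 genes changed at each size, 54% were recovered at a log2 change of 0.3, 78% at 0.5, 94% at 1 and 100% at 2, with 12 false calls among 175. Without simulated change, 0 genes and 0 lists were called. The simulated genes varied independently of each other, so the 0 lists do not show how the list test behaves when genes are correlated. All files of the series that hold values were used.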

Results

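Messenger RNA was measured in the wild-type haploid Saccharomyces cerevisiae strain CEN.PK113-7D, a laboratory strain of mating type a, grown aerobically in shake flasks. BSA had been added to 3 cultures, and 3 control cultures were grown without it. BSA is by its usual meaning bovine serum albumin, a soluble protein of cow serum, although the labels give only the abbreviation. The amount added and the composition of the medium are not given in the sources used here. Each culture gave 1 array, and the labels call the 3 arrays of each group biological replicates. The labels differ on the time of sampling: the protocol gives 48 h, whereas the design text places sampling in the first phase of growth on glucose. The labels alone thus do not settle the growth phase. Control means of the glucose-repressed genes PCK1 (10.88), ADH2 (9.03) and FBP1 (8.72) lay above the array medians. These few genes speak for a state past the first phase on glucose, but do not settle it. The deposited table held log2 expression values of 5705 probe sets, from which 5657 genes were tested. The medians of the 6 arrays lay between 7.56 and 7.61, and the number of arrays limits the precision.

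Arrays of one group were closer to each other than to any array of the other group. The SD over genes of the difference between 2 arrays was 0.0567 to 0.198 (log2) within groups and 0.625 to 0.732 between groups, and the first principal component, which parted the groups, held 92.7% of the variance. Control replicates 2 and 3 were the closest pair, with an SD of 0.0567 and no gene that differed by more than 0.5. The other 5 pairs within a group had SDs of 0.117 to 0.198. The 2 control arrays were kept as separate replicates, and the main counts are also given with their mean as 1 replicate.

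The comparison implied by the design sets the cultures with BSA against the cultures without it and asks how gene expression differed when BSA was present. With BSA, genes for cytoplasmic ribosomal proteins, ribosome assembly and the secretory pathway had lower transcript levels. Genes of the respiratory chain, of trehalose and glycogen metabolism, of the general stress response, of sulfur assimilation and of iron uptake had higher levels. Of the 5657 genes, 4268 (75.4%) passed an adjusted p of 0.05 in limma, 1603 higher and 2665 lower with BSA. Larger changes went mostly the other way, since 398 genes were at least 2-fold higher and 111 at least 2-fold lower, and 77 were at least 4-fold higher and 6 at least 4-fold lower. In 4498 genes (79.5%) the values of the groups did not overlap, against 10% expected by chance for 3 arrays against 3.

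The median log2 fold change of all genes was -0.13, so the split into higher and lower genes depends on the scaling between arrays. With each array centred on its median deviation from the gene means, 2074 genes were higher and 2056 lower (50.2% of the called genes higher, against 37.6% as deposited), and after cyclic loess normalization 1986 were higher and 2073 lower (48.9%). Medians of gene groups are therefore also given relative to the median of all genes. With control replicates 2 and 3 counted as 1 sample, 3953 genes passed, 1479 higher and 2474 lower. This count and both scalings were chosen after the data were seen.

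**Figure D1:**
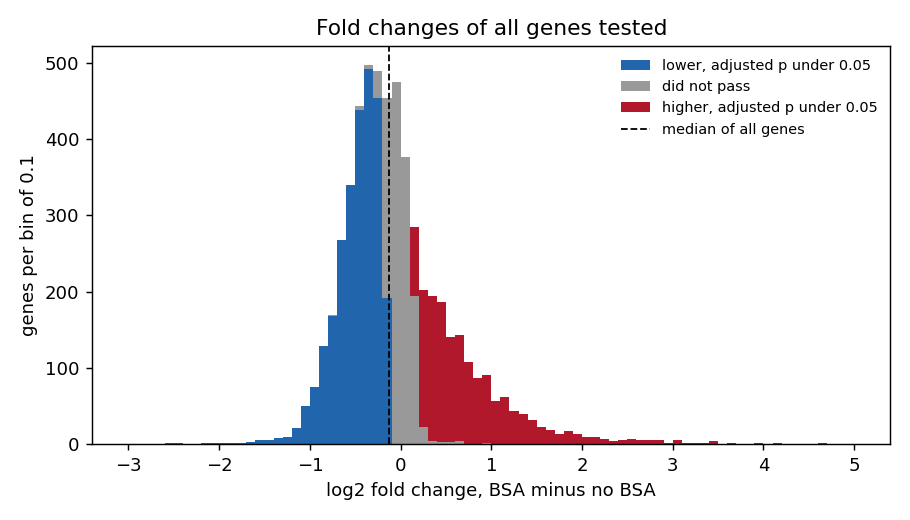
Histogram of the log2 fold changes (BSA minus no BSA, x axis) of the 5657 genes in bins of 0.1, with the number of genes on the y axis. Red bars are the 1603 genes called higher, blue bars the 2665 called lower and grey bars genes that did not pass; the dashed line marks the median of all genes, -0.13, and the tail on the higher side is the longer one.

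The gene that rose furthest was CYC7 (YEL039C), which encodes the isoform of cytochrome c known from cells short of oxygen. Its log2 expression went from 6.64 ± 0.17 to 11.24 ± 0.28 (mean ± SD, n = 3 arrays per group), a 24.3-fold rise (limma adjusted p = 9.89e-07). ICY1 rose by 4.15 ± 0.14 (log2 fold change ± SE) and ROG3, an arrestin-related protein, by 3.99 ± 0.16. The 12 genes that rose furthest also held the sulfate permease gene SUL2 (3.40 ± 0.10), the GSK-3 family kinase gene MRK1 (3.46 ± 0.20) and CIP1, an inhibitor of cyclin-dependent kinase (3.33 ± 0.13). SPI1, a cell wall protein induced by stress, rose by 3.22 ± 0.23, and RSB1, linked to the transport of sphingoid bases, by 3.15 ± 0.10. The others were YNR014W (3.70), YKL068W-A (3.48), TDA6 (3.42) and AIM33 (3.13), whose functions are little known.

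Decreases were smaller. NFG1 (YLR042C), a negative regulator of filamentous growth, fell furthest, from 8.26 ± 0.35 to 5.68 ± 0.07 (SD, n = 3), which is 6.01-fold (limma adjusted p = 9.02e-06). ARO10, a decarboxylase that acts on the keto acids of aromatic amino acids, changed by -2.41 ± 0.30 (SE), and CHA1, which deaminates serine and threonine, by -2.19 ± 0.10. DAL4, the allantoin permease gene, changed by -1.97 ± 0.08. The cell surface and cell wall genes SVS1 (-2.41), PRM5 (-1.77) and PUN1 (-1.60) and AFB1 (-1.66), which encodes a barrier to a-factor, also fell. The remaining genes were CPP3 (-2.10), MNC1 (-2.05), YNR065C (-1.87) and YIL108W (-1.69). All 24 genes, higher and lower, passed the threshold under every alternative that kept them.

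**Figure D2:**
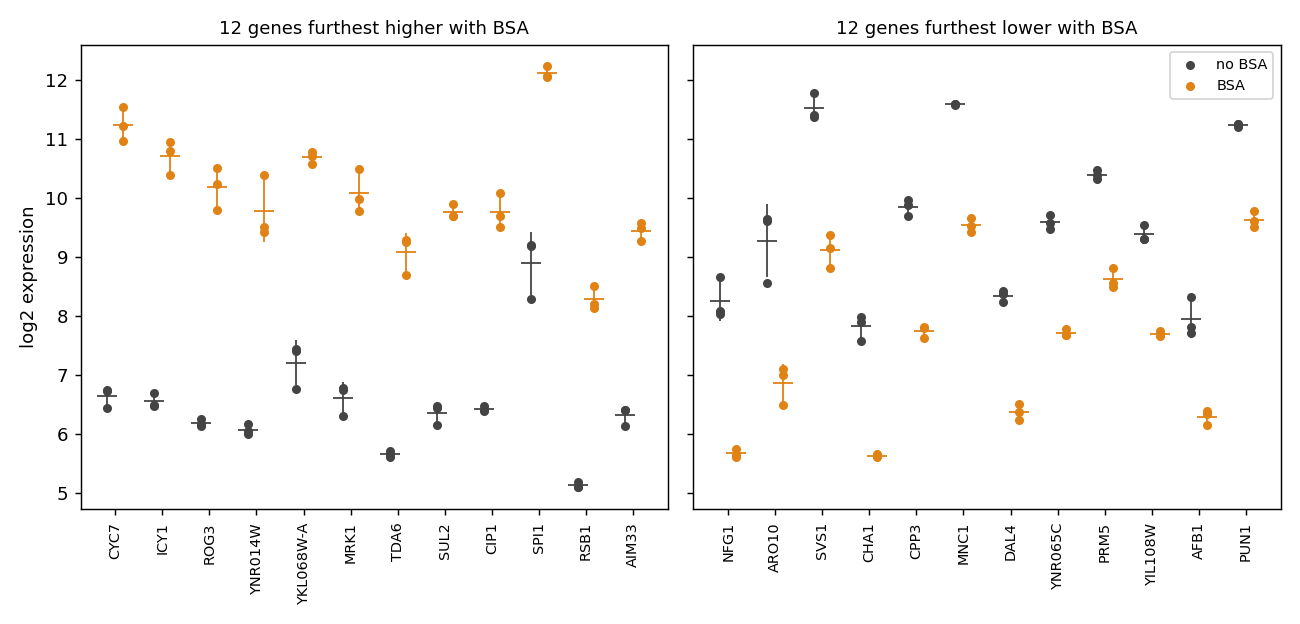
Log2 expression (y axis) of the 12 genes that rose furthest and the 12 that fell furthest with BSA (x axis). Dots are single arrays, 3 without BSA (grey) and 3 with BSA (orange), and bars give the mean ± SD; the groups do not overlap for any of these genes, and CYC7 has the widest gap, from 6.64 to 11.24.

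Genes for the protein synthesis machinery of the cytoplasm were lower with BSA. Of 129 measured genes for cytoplasmic ribosomal proteins, 126 fell and 1 rose, with a median log2 fold change of -0.87, or -0.74 relative to all genes. RPL12B went from 10.32 ± 0.01 to 9.34 ± 0.04 (SD, n = 3), RPL29 changed by -1.10 ± 0.06 (SE), RPS22B by -1.52 ± 0.08 and RPS9B by -1.07 ± 0.06. RPS27A rose by 1.15 ± 0.18, whereas RPS9A (-0.28 ± 0.13) and RPS30A (0.11 ± 0.08) did not pass. RPS9A passed as lower without control replicate 1 (adjusted p = 0.00937) or BSA replicate 3 (adjusted p = 0.0433), with array weights (adjusted p = 0.00402) and after quantile normalization (adjusted p = 0.0187), and RPS30A passed as higher with arrays centred on the median deviation (adjusted p = 0.0288). Many ribosomal proteins have 2 near-identical gene copies, and 28 of the 129 genes were read by probe sets that can share signal between copies. Of 55 ribosome biogenesis genes, 47 fell, with a median of -0.51, or -0.38 relative to all genes. NOP58 and GAR1, core proteins of small nucleolar ribonucleoproteins, changed by -1.16 ± 0.07 and -0.89 ± 0.05, NUG1 by -1.02 ± 0.05 and SPB1 by -0.66 ± 0.05. In this list 3 genes rose: DRS1 (1.38 ± 0.13), IMP4 (0.64 ± 0.07) and ENP1 (0.25 ± 0.09). The ENP1 call was lost without control replicate 1, 2 or 3 or BSA replicate 2 or 3 (adjusted p = 0.0511 to 0.135). Adjusted over the list alone, the counts were the same for ribosomal proteins, and 47 fell and 4 rose for ribosome biogenesis, NOP7 (0.16 ± 0.07) being the fourth. NOP7 also passed over all genes under all 4 scalings (limma adjusted p = 0.0041 to 0.0234) and without BSA replicate 3 (adjusted p = 0.0365). Against all other genes, camera gave an adjusted p = 5.67e-16 for ribosomal proteins (adjusted p = 0.61 with an estimated correlation) and an adjusted p = 3.01e-05 for ribosome biogenesis (adjusted p = 0.63 with an estimated correlation).

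Genes of protein secretion fell as well. Of 57 secretory pathway genes, 47 fell and 6 rose, with a median of -0.55, or -0.42 relative to all genes. SEC61, the channel through which proteins enter the endoplasmic reticulum (ER), went from 9.85 ± 0.0035 to 8.88 ± 0.03 (SD, n = 3). SEC63, a partner of that channel, changed by -0.75 ± 0.05 (SE) and the vesicle coat gene SEC24 by -0.85 ± 0.05. SEC17, which acts in the recycling of membrane fusion complexes, was the member with the smallest p and rose by 1.10 ± 0.05. In the list of ER folding and the unfolded protein response, 20 of 28 genes fell, with a median of -0.40, or -0.26 relative to all genes. FPR2 (-0.84 ± 0.05), SSS1 (-0.90 ± 0.06), ERJ5 (-0.57 ± 0.05) and CWH41 (-0.79 ± 0.08) had the smallest p, and the 2 genes that rose, UBC7 (0.82 ± 0.10) and HRD1 (0.26 ± 0.05), act in the degradation of misfolded ER proteins. Of 33 protein glycosylation genes, 19 fell, with a median of -0.28, or -0.14 relative to all genes. These included DPM1 (-0.78 ± 0.05), ALG12 (-0.82 ± 0.05), ALG5 (-0.79 ± 0.05) and PMT2 (-0.69 ± 0.05), whereas the mannosyltransferase genes MNN5 (0.70 ± 0.06) and MNN1 (0.71 ± 0.09) rose. The counts of these 3 lists were the same when adjusted over the list alone.

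By camera, the secretory pathway list had an adjusted p = 0.000171 (adjusted p = 0.61 with an estimated correlation), ER folding an adjusted p = 0.0489 (adjusted p = 0.61 with an estimated correlation) and glycosylation an adjusted p = 0.0366 (adjusted p = 0.70 with an estimated correlation). The call of ER folding was lost without control replicate 2 (adjusted p = 0.054), without BSA replicate 3 (adjusted p = 0.0554) and without the dimmest 25% or the dimmer 50% of genes (adjusted p = 0.0934 and 0.227), in a range of 0.0277 to 0.227 over the 19 alternatives that kept the preset correlation. Glycosylation lost its call without control replicate 1 (adjusted p = 0.0688), without BSA replicate 3 (adjusted p = 0.0503), with array weights (adjusted p = 0.053) and without the dimmer 50% of genes (adjusted p = 0.0654), in a range of 0.0169 to 0.0688. Of 10000 random lists of equally bright genes, 9.65% had a median as low as that of glycosylation. Its fall is thus not set apart from such lists, and 2665 of all 5657 genes fell.

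Nearly all genes of the respiratory chain were higher with BSA, and of the genes of mitochondrial ribosomes more rose than fell. Of 39 genes of the respiratory chain and ATP synthase, 37 rose and 0 fell (0 also at an unadjusted p under 0.05 in limma), with a median of 0.59, or 0.73 relative to all genes. After CYC7, the member with the smallest p was HAP4, the regulatory subunit of the activator of respiratory genes, which went from 9.58 ± 0.24 to 11.41 ± 0.08 (SD, n = 3). COX5A, a subunit of cytochrome c oxidase, rose by 0.95 ± 0.06 (SE) and RIP1, the Rieske iron-sulfur protein, by 1.24 ± 0.08, whereas ATP1 (-0.06 ± 0.07) and NDE2 (-0.03 ± 0.09) did not pass. Of 72 mitochondrial ribosomal protein genes, 34 rose and 15 fell, with a median of 0.14, or 0.27 relative to all genes. MRP49 (1.28 ± 0.07), MRPL16 (1.08 ± 0.07), MRPL31 (1.16 ± 0.08) and MRP1 (0.93 ± 0.07) had the smallest p. Both lists kept their counts when adjusted over the list alone. The camera adjusted p was 1.26e-11 for the respiratory list (adjusted p = 0.61 with an estimated correlation) and 0.000504 for mitochondrial ribosomal proteins (adjusted p = 0.64 with an estimated correlation).

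Genes of reserve carbohydrates and of the general stress response rose. Of 21 trehalose and glycogen genes, 15 rose and 1 fell, with a median of 0.79, or 0.92 relative to all genes. GSY1, a glycogen synthase, went from 6.69 ± 0.02 to 9.30 ± 0.30 (SD, n = 3). PIG2, a putative targeting subunit of the phosphatase that acts on glycogen synthase, rose by 2.09 ± 0.08 (SE), ATH1, a trehalase, by 1.35 ± 0.06 and the phosphoglucomutase gene PGM2 by 1.58 ± 0.07. TPS3, a regulatory subunit of trehalose synthase, changed by -0.52 ± 0.06. Of 37 genes of the Msn2/4 type general stress response, 29 rose, with a median of 0.48, or 0.61 relative to all genes. YGP1, a secreted glycoprotein, rose by 2.89 ± 0.10 and GRE1 by 1.64 ± 0.07, and PGM2 is also on this list. The 3 that fell were the aldehyde dehydrogenase gene ALD4 (-1.05 ± 0.07), the chaperone gene SSA3 (-0.75 ± 0.27) and the glucokinase gene GLK1 (-0.24 ± 0.05). The SSA3 call was lost without control replicate 2 or 3 or BSA replicate 1 (adjusted p = 0.102 to 0.11) and after cyclic loess (adjusted p = 0.0544). With arrays centred on the median deviation neither SSA3 (adjusted p = 0.0701) nor GLK1 (adjusted p = 0.0801) passed. Of 27 oxidative stress genes, 14 rose and 6 fell, with a median of 0.15, or 0.28 relative to all genes. GSH1, which starts glutathione synthesis, rose by 1.72 ± 0.05, cytochrome c peroxidase CCP1 by 2.79 ± 0.14, the peroxiredoxin gene AHP1 by 1.15 ± 0.09 and the methionine sulfoxide reductase gene MXR1 2.82-fold. Adjusted over the list alone, the counts of all 3 lists were the same.

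The camera adjusted p was 1.62e-05 for trehalose and glycogen, 1.55e-06 for the general stress response and 0.0366 for oxidative stress (adjusted p = 0.61 for each with an estimated correlation). The call of oxidative stress was lost without BSA replicate 3 (adjusted p = 0.0503), after quantile normalization (adjusted p = 0.0809) and without the dimmer 50% of genes (adjusted p = 0.0654), in a range of 0.0157 to 0.0809 over 19 alternatives. Among 10000 random lists of equally bright genes, the oxidative stress median lay at percentile 92.26, so its rise is not set apart from such lists.

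Genes of sulfur assimilation and of the iron regulon rose together. Of 31 genes of sulfur assimilation and methionine metabolism, 23 rose, with a median of 0.88, or 1.01 relative to all genes. After SUL2 came MET32, a regulator of the pathway, which went from 7.79 ± 0.22 to 10.56 ± 0.03 (SD, n = 3). MET16, the phosphoadenylylsulfate reductase gene, rose by 2.56 ± 0.10 (SE) and the regulator gene MET28 by 1.90 ± 0.07. The 3 that fell were MHT1 (-0.57 ± 0.08) and MMP1 (-0.56 ± 0.20), which act in the use of S-methylmethionine, and STR2 (-0.27 ± 0.05). The MMP1 call was lost without control replicate 2 or 3 or BSA replicate 1, 2 or 3 (adjusted p = 0.0563 to 0.106) and under 3 of the 4 scalings (adjusted p = 0.0512 to 0.0995). Of 29 iron regulon genes, 21 rose, with a median of 0.82, or 0.95 relative to all genes. FIT2, a cell wall mannoprotein that retains iron-siderophores, went from 8.52 ± 0.12 to 11.32 ± 0.18 (SD, n = 3). The mitochondrial iron carrier gene MRS4 rose by 1.92 ± 0.11 (SE), the iron-sulfur scaffold gene ISU1 by 0.88 ± 0.05 and AFT2, an activator of iron regulon genes, by 0.90 ± 0.05. FRE4, a ferric reductase gene, was the only one called lower (-0.30 ± 0.11), a call lost without control replicate 2 or 3 or BSA replicate 1 or 3 (adjusted p = 0.0922 to 0.134) and under all 4 scalings (adjusted p = 0.0511 to 0.187), while without BSA replicate 2 there were 2 such genes, FRE4 and FIT1. The FRE4 signal was dim, with means of 5.81 without and 5.51 with BSA, below the first quartile of every array. For both lists the counts adjusted over the list alone were the same. The camera adjusted p was 1.09e-06 for the sulfur list and 8.79e-06 for the iron list (adjusted p = 0.61 for each with an estimated correlation).

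Genes that answer to zinc, copper and phosphate moved in both directions, and none of these 3 lists passed camera. Of 18 genes of the zinc regulon, 8 rose, the cell surface protein gene ZPS1 by 2.23 ± 0.21 (SE), and 5 fell (median 0.42, adjusted p = 0.0735). The list passed without control replicate 1 (adjusted p = 0.0157), with array weights (adjusted p = 0.0268) and without the dimmest 25% of genes (adjusted p = 0.0469), in a range of 0.0157 to 0.123. The 5 that fell were the peroxiredoxin gene TSA1 (-0.70 ± 0.09), ZRG17 (-0.38 ± 0.07), MCD4 (-0.24 ± 0.07), ADH4 (-0.22 ± 0.05) and IZH4 (-0.15 ± 0.05). The IZH4 signal was dim, with means of 5.78 without and 5.63 with BSA, below the first quartile of every array. MCD4 did not pass with arrays centred on the median deviation or after cyclic loess (adjusted p = 0.15 and 0.25), ADH4 under these or quantile normalization (adjusted p = 0.0667 to 0.393) and IZH4 under any of the 4 scalings (adjusted p = 0.0726 to 0.746), nor did IZH4 without control replicate 2 or 3 or BSA replicate 1 or 2 (adjusted p = 0.0579 to 0.119). The zinc transporter genes ZRT1 (0.17 ± 0.34), ZRT2 (0.56 ± 0.27) and ZRT3 (0.27 ± 0.18) did not pass, but without control replicate 1 they rose by 0.62, 0.92 and 0.50 (adjusted p = 0.00145, 6.83e-05 and 0.000648), and they also passed with array weights (adjusted p = 0.0119, 0.000125 and 0.000925). Of 12 copper genes, 6 rose, the regulator gene MAC1 by 0.69 ± 0.09, and 2 fell (median 0.29, camera adjusted p = 0.126). The 2 were FRE7 (-0.60 ± 0.22) and the metallothionein gene CUP1-1 (-0.44 ± 0.16), the latter read by a probe set that can share signal. Neither FRE7 nor CUP1-1 passed without control replicate 2 or 3 or BSA replicate 1, FRE7 was also lost without control replicate 1 or BSA replicate 3, and CUP1-1 without BSA replicate 2 (adjusted p = 0.0527 to 0.111). FRE7 did not pass with arrays centred on the median deviation or after cyclic loess (adjusted p = 0.083 and 0.102), nor CUP1-1 after quantile normalization or either kind of centring (adjusted p = 0.0562 to 0.124). Of 17 phosphate genes, 7 rose, among them the phosphate transporter gene PHO84 (1.08 ± 0.08), and 4 fell (median -0.0012, adjusted p = 0.233). The 4 were the sodium-phosphate cotransporter gene PHO89 (-1.05 ± 0.07), GIT1 (-0.71 ± 0.08), PHO81 (-0.62 ± 0.07) and PHO11 (-0.45 ± 0.05), the last read by a probe set that can share signal. ZPS1, ZRT1, ZRT2, ZRT3, MAC1 and PHO84 were chosen after their values were seen. Adjusted over the list alone, 5 copper genes rose and the other counts were the same.

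Most genes of ergosterol synthesis fell, while other lipid lists and the genes of low oxygen were mixed. Of 26 ergosterol genes, 18 fell, ERG2 by -0.87 ± 0.11 (SE) and ERG1 by -0.83 ± 0.12, and ERG3 rose by 0.69 ± 0.18 (median -0.46, or -0.32 relative to all genes). Without control replicate 1, 3 genes rose, ERG3, ERG5 and ERG25. The list just missed the threshold of camera (adjusted p = 0.0501) and passed in 12 of 19 alternatives, among them those without control replicate 2 (adjusted p = 0.0191) or 3 (adjusted p = 0.0193) and all 4 scalings, in a range of 0.00832 to 0.114. Of 26 fatty acid and phospholipid genes, 7 rose and 10 fell as deposited, but 9 rose and 7 fell after cyclic loess (median -0.02, camera adjusted p = 0.762). The fatty acid synthase genes FAS1 (-0.76 ± 0.05) and FAS2 (-0.84 ± 0.07) fell, and OPI1, a repressor of phospholipid synthesis genes, rose by 1.26 ± 0.08. Of 33 beta-oxidation and peroxisome genes, 15 rose, the catalase gene CTA1 by 1.41 ± 0.08, and 12 fell, the acyl-CoA oxidase gene POX1 by -0.86 ± 0.06 (median 0.12, camera adjusted p = 0.088). Of 23 hypoxic and anaerobic genes, 11 rose and 8 fell (median 0.03, camera adjusted p = 0.088), with 5 that fell without BSA replicate 3. The heme synthesis gene HEM13 rose by 2.14 ± 0.10 and ROX1, a repressor of hypoxic genes, by 1.04 ± 0.06. This list passed camera without the dimmest 25% of genes (adjusted p = 0.0242, in a range of 0.0242 to 0.101). All genes of this paragraph except ERG3, ERG5 and ERG25 were chosen after their values were seen, and none of the 4 lists changed its counts when adjusted over the list alone.

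**Figure D3:**
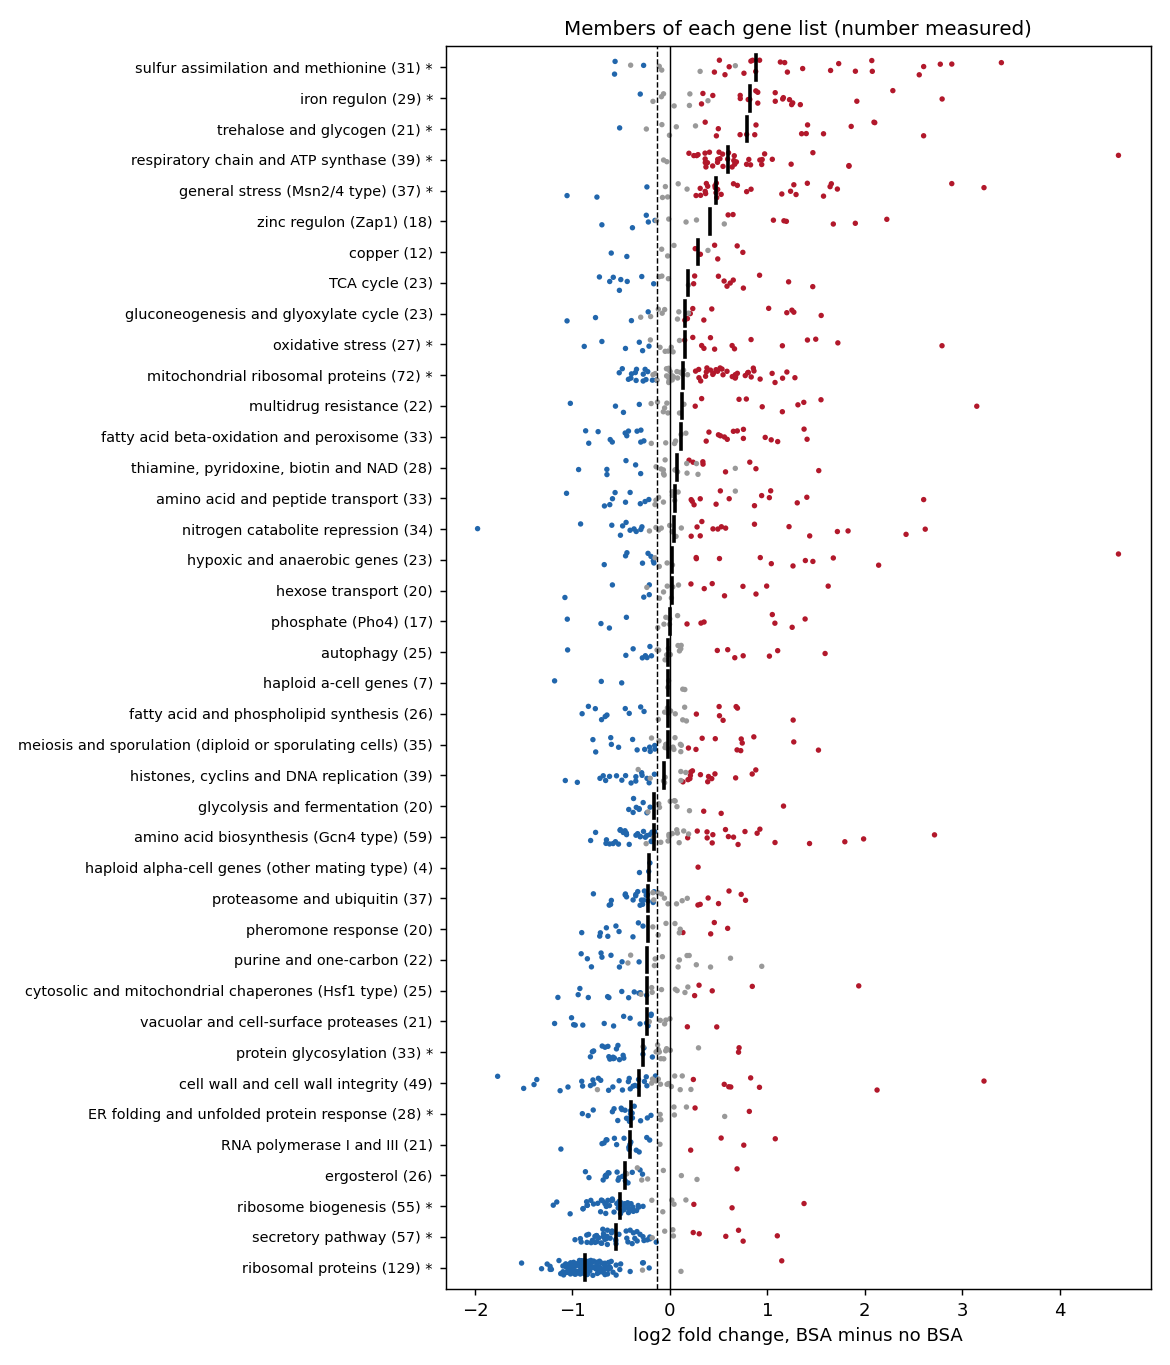
Log2 fold change (BSA minus no BSA, x axis) of the measured members of the 40 gene lists (y axis, number measured in brackets). Red dots are members called higher, blue dots members called lower and grey dots members that did not pass; black ticks are list medians, the dashed line is the median of all genes (-0.13), and an asterisk marks the 12 lists past the camera threshold with the preset correlation, from sulfur assimilation (median 0.88) to ribosomal proteins (median -0.87).

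In all, 12 of the 39 lists tested with camera passed with the preset correlation of 0.01, 7 higher and 5 lower, and 19 passed at an unadjusted p under 0.05. When camera estimated the correlation between genes from the arrays, which 2 groups of 3 leave poorly known, 0 lists passed, adjusted or not. By fry, which asks only whether the genes of a list move on balance one way, 30 passed. The direction of the 12 lists was the same under every alternative run, scalings included. The list p-values therefore rest on the preset correlation, and the counts of members stand beside them.

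Lists that concern nitrogen supply and protein breakdown moved in both directions and did not pass. Of 34 genes under nitrogen catabolite repression, 15 rose and 11 fell (median 0.04, camera adjusted p = 0.172). The genes with the smallest p were those of 4-aminobutyrate use: UGA2 went from 7.39 ± 0.05 to 10.01 ± 0.10 (SD, n = 3), UGA4 rose by 2.42 ± 0.10 (SE) and UGA1 by 1.83 ± 0.06, followed by DAL4, which fell. Of 21 vacuolar and cell-surface protease genes, 14 fell (median -0.24, or -0.11 relative to all genes, camera adjusted p = 0.0578). The vacuolar peptidase genes CPS1 (-1.01 ± 0.06), APE3 (-0.99 ± 0.08) and APE1 (-0.97 ± 0.08) and the secreted protease gene BAR1 (-1.18 ± 0.10) had the smallest p. The 2 that rose were AXL1 (0.48 ± 0.07) and DAP2 (0.18 ± 0.07), and DAP2 lost its call without control replicate 2 or 3 or BSA replicate 2 or 3 (adjusted p = 0.0937 to 0.125) and after quantile normalization (adjusted p = 0.078). The protease list passed camera without control replicate 3 (adjusted p = 0.046), without the dimmest 25% of genes (adjusted p = 0.0481), after quantile normalization (adjusted p = 0.0297) and after cyclic loess (adjusted p = 0.0361), in a range of 0.0297 to 0.0815. Of 33 amino acid and peptide transport genes, 14 rose and 10 fell (median 0.05, camera adjusted p = 0.137), among them the methionine permease gene MUP3 (2.60 ± 0.13), STP1 (1.02 ± 0.07) and OPT1 (1.40 ± 0.10), which rose, and the tryptophan permease gene TAT2 (-1.06 ± 0.06). The general amino acid permease gene GAP1 (-0.14 ± 0.16) and the peptide transporter gene PTR2 (0.03 ± 0.19), chosen after their values were seen, did not pass. Of 59 amino acid biosynthesis genes, 18 rose and 29 fell as deposited, but 23 rose and 17 fell with arrays centred on the median deviation. Their median was -0.16 (-0.03 relative to all genes), their mean was 0.08, camera pointed up (adjusted p = 0.679) and fry down. ARG8 (1.99 ± 0.06), SER3 (1.79 ± 0.09) and LYS20 (2.71 ± 0.14) rose, and ARO4 changed by -0.81 ± 0.05. Adjusted over the list alone, the counts of all 4 lists were the same.

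Genes of central carbon metabolism also moved in both directions, and none of these 4 lists passed camera. Of 20 glycolysis and fermentation genes, 9 fell and 3 rose as deposited (median -0.16, adjusted p = 0.863), but 4 fell and 6 rose with arrays centred on the median deviation. The 3 were the pyruvate decarboxylase gene PDC6 (1.17 ± 0.10), HXK1 (0.53 ± 0.13) and TDH1 (0.35 ± 0.06). Of 20 hexose transport genes, 8 rose and 5 fell (median 0.02, adjusted p = 0.193). MTH1, which encodes a repressor of transporter genes rather than a transporter, rose by 1.62 ± 0.16 and HXT3 by 0.99 ± 0.10. The 5 that fell were HXT2 (-1.08 ± 0.12), HXT5 (-0.59 ± 0.12), HXT14 (-0.27 ± 0.06), HXT11 (-0.21 ± 0.06) and HXT10 (-0.21 ± 0.08). The last 2 calls were lost without control replicate 2 (adjusted p = 0.0748 and 0.11) or BSA replicate 3 (adjusted p = 0.0605 and 0.0697), which left 3, and HXT10 also without control replicate 3 (adjusted p = 0.116) or BSA replicate 1 (adjusted p = 0.0921). With arrays centred on the median deviation, 2 genes fell, and HXT14 (adjusted p = 0.0833), HXT11 (adjusted p = 0.287) and HXT10 (adjusted p = 0.332) did not pass. After cyclic loess HXT11 (adjusted p = 0.112) and HXT10 (adjusted p = 0.0757) were lost, and HXT10 also with arrays centred on their medians (adjusted p = 0.0646). HXT2, HXT14, HXT11 and HXT10 were dim, with group means of 5.07 to 6.54, below the first quartile of every array (6.76 to 6.91). Of 23 genes of gluconeogenesis and the glyoxylate cycle, 11 rose (median 0.15, adjusted p = 0.0635), with CAT8, an activator of these genes, at 1.25 ± 0.07 and FBP1, fructose-1,6-bisphosphatase, at 1.20 ± 0.23. The 4 that fell were ALD4, the alcohol dehydrogenase gene ADH2 (-0.76 ± 0.15), PCK1 (-0.39 ± 0.15) and GUT2 (-0.22 ± 0.06). PCK1 lost its call without control replicate 1 or 3 or BSA replicate 1 or 3 (adjusted p = 0.058 to 0.115) and under both kinds of centring and cyclic loess (adjusted p = 0.0566 to 0.126), and GUT2 when arrays were centred on the median deviation (adjusted p = 0.182). This list passed camera without control replicate 1 (adjusted p = 0.0244), without BSA replicate 1 (adjusted p = 0.0291) and with array weights (adjusted p = 0.0167), in a range of 0.0167 to 0.394. Of 23 TCA cycle genes, 11 rose, KGD2 by 1.47 ± 0.05, and 8 fell (median 0.19, adjusted p = 0.144). MTH1, HXT3, CAT8, FBP1 and KGD2 were chosen after their values were seen. None of these counts changed when adjusted over the list alone.

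Markers of other cell types or states that a yeast culture could hold did not move together. The strain is of mating type a, and of 7 a-cell genes 3 fell: BAR1, the a-factor exporter gene STE6 (-0.70 ± 0.07) and the agglutinin subunit gene AGA2 (-0.49 ± 0.05). None of the 7 rose as deposited, in limma with or without adjustment (median -0.02, camera adjusted p = 0.606), and the other 4, chosen after their values were seen, were MFA1 (-0.01 ± 0.05), STE2 (-0.02 ± 0.11), MFA2 (0.13 ± 0.10) and ASG7 (0.15 ± 0.07). MFA2 and ASG7 passed as higher without control replicate 1 (adjusted p = 0.00575 and 0.0159) and with arrays centred on the median deviation (adjusted p = 0.0446 and 0.00971), and ASG7 also under the other 3 scalings (adjusted p = 0.00495 to 0.0366). Both passed with array weights (adjusted p = 0.00813 and 0.00202), and MFA1 passed as lower after quantile normalization (adjusted p = 0.0212). Of 4 genes of the other mating type, too few for camera, MF(ALPHA)1 rose by 0.29 ± 0.07, and SAG1 (-0.31 ± 0.06), STE3 (-0.22 ± 0.06) and MF(ALPHA)2 (-0.20 ± 0.06) fell. Signals were dim for MF(ALPHA)1 (means of 5.45 without and 5.74 with BSA), MF(ALPHA)2 (5.44 and 5.24) and STE3 (6.57 and 6.35). These means lay below the first quartile of every array (6.76 to 6.91), so such shifts may be background. The STE3 and MF(ALPHA)2 calls were lost without control replicate 2 (adjusted p = 0.0565 and 0.0719) or control replicate 3 (adjusted p = 0.057 and 0.0678) and with arrays centred on the median deviation (adjusted p = 0.247 and 0.294). After cyclic loess SAG1 and STE3 did not pass (adjusted p = 0.095 and 0.52), nor STE3 after quantile normalization (adjusted p = 0.105). Of 20 pheromone response genes, 10 fell, the regulator gene STE12 by -0.65 ± 0.06, and 4 rose (median -0.23, camera adjusted p = 0.493). The 4 were FUS2 (0.59 ± 0.11), STE4 (0.46 ± 0.07), PRM4 (0.42 ± 0.05) and FAR1 (0.13 ± 0.05), and the FAR1 call was lost without control replicate 1, 2 or 3 or BSA replicate 1 or 2 (adjusted p = 0.0575 to 0.101). Of 35 meiosis and sporulation genes, 11 rose and 12 fell as deposited (median -0.02, camera adjusted p = 0.493), and 14 rose and 8 fell with arrays centred on the median deviation. SPS100 rose by 1.52 ± 0.13 and SPO22 changed by -0.79 ± 0.09. STE12, SPS100 and SPO22 were chosen after their values were seen. Adjusted over the list alone, the counts of all 4 lists were the same.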

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

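The number of genes past the threshold (4268) stayed within 1.5 times under every alternative except 2. Without the dimmer 50% of genes 2232 passed, 1045 higher and 1187 lower, from fewer genes tested, and asking for at least 2-fold left 509, 398 higher and 111 lower. Elsewhere the count ran from 3316 (without the dimmest 25% of genes) to 4653 (array weights), with 3991 in a plain t-test, 3672 at an adjusted p under 0.01, 4185 after quantile normalization, 4213 with arrays centred on their medians and 4182 without probe sets that can share signal. Leaving out 1 array gave 3912 to 4277 genes, 1453 to 1597 higher and 2459 to 2680 lower, and 9 to 15 lists. Lists past the threshold (12) fell to 0 with an estimated correlation and rose to 30 with fry, and were 11 to 16 under the other alternatives that left out no array. Over named genes and alternatives, 4045 values kept their side of the threshold, 132 lost their call and 36 gained one. Of the values that passed in the main fit or the alternative, 0 reversed their direction. Where a gene passed in neither fit, its direction was not compared. In the plain t-test the calls lost were those of ENP1, DAP2, FRE4, MMP1, SSA3, HXT10, PCK1, HSF1, SSC1, FRE7, CUP1-1 and ERG3 (adjusted p = 0.0587 to 0.135), and the cause was not tested. With control replicates 2 and 3 as 1 sample, ENP1, DAP2, FRE4, MMP1, SSA3, HXT10, HXT11, FAR1, IZH4, STE3, MF(ALPHA)2, CUP1-1 and FRE7 lost their calls (adjusted p = 0.0523 to 0.117), from fewer samples. The labels give both groups the same replicate numbers, but same-numbered arrays deviated together only weakly (correlations of 0.103, 0.0187 and 0.0426), and control replicates 2 and 3 each correlated best with a BSA array of another number (0.0868 and 0.117). With the replicate block 4266 genes passed (1597 higher, 2669 lower) and 12 lists, of which ergosterol (adjusted p = 0.032) took the place of ER folding (adjusted p = 0.0517). No other list changed its call. Among named genes, the block removed the limma calls of DAP2 (adjusted p = 0.0638), PCK1 (adjusted p = 0.0736), SSC1 (adjusted p = 0.0561) and FAR1 (adjusted p = 0.0636). It added calls of RPS9A as lower (adjusted p = 0.0168) and ASG7 as higher (adjusted p = 0.0374). No pseudocount was tried, since the deposited values are logarithms. Of the genes in the dimmest 25%, 66.3% passed, against 81.6% in the brightest 25%, and whether dim signals or fewer real changes lie behind this was not tested.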

Other observations

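In this part the tests of respiratory genes after cyclic loess, glucose-repressed genes, amino acid starvation, metal withdrawal, the near-identical arrays and the gene pairs were chosen after the results were seen.

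Most genes of RNA polymerases I and III fell with BSA, while proteasome, chaperone and autophagy genes moved in both directions, and none of these 4 lists passed camera. Of 21 genes of RNA polymerases I and III, 16 fell, the polymerase III subunit gene RET1 by -1.12 ± 0.05 (SE), and 4 rose: RPC31 (1.08 ± 0.07), RRN3 (0.76 ± 0.06), RPA14 (0.53 ± 0.09) and RPC37 (0.21 ± 0.06), the last lost without control replicate 2 (adjusted p = 0.0536). Their median was -0.41, or -0.28 relative to all genes (camera adjusted p = 0.126). Of 37 proteasome and ubiquitin genes, 21 fell, PRE2 by -0.78 ± 0.07, and 7 rose, UFD1 by 0.78 ± 0.06 (median -0.22, camera adjusted p = 0.522). Of 25 chaperone genes of the cytosol and mitochondria, 12 fell, 11 adjusted over the list alone, with SSA2 at -1.15 ± 0.14 and SSB2 at -0.94 ± 0.05, and 5 rose (median -0.24, camera adjusted p = 0.679). The 5 were APJ1 (1.94 ± 0.09), SSE2 (0.85 ± 0.13), HSP78 (0.43 ± 0.09), SSC1 (0.30 ± 0.11) and HSF1 (0.25 ± 0.09). HSF1 was lost without control replicate 1 (adjusted p = 0.068), HSF1 and SSC1 without BSA replicate 2 (adjusted p = 0.0909 and 0.0534) or 3 (adjusted p = 0.0822 and 0.0693), which left 3, and SSC1 without BSA replicate 1 (adjusted p = 0.101). Both were also lost after quantile normalization (adjusted p = 0.0927 and 0.0855). Of 25 autophagy genes, 7 rose, ATG3 by 1.59 ± 0.07, and 8 fell, ATG5 by -1.05 ± 0.05, as deposited, but 12 rose and 3 fell with arrays centred on the median deviation (median -0.02, camera adjusted p = 0.304). The other 3 lists of this paragraph kept their counts when adjusted over the list alone, and RET1, PRE2, UFD1, SSA2, SSB2, ATG3 and ATG5 were chosen after their values were seen.

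Among cell wall genes, 28 of 49 fell and 8 rose (median -0.32, or -0.19 relative to all genes), with CRH1 falling 2.83-fold and NCW2 changing by -1.37 ± 0.08 (SE) against a rise of CWP1 by 2.13 ± 0.07. The list missed the threshold of camera (adjusted p = 0.162) and passed without the dimmest 25% or the dimmer 50% of genes (adjusted p = 0.0205 and 0.00715, in a range of 0.00715 to 0.226). Of 22 multidrug resistance genes, 10 rose, after RSB1 among others the weak acid exporter gene PDR12 (1.55 ± 0.14), and 4 fell: PDR5 (-1.02 ± 0.15), QDR2 (-0.56 ± 0.06), PDR1 (-0.48 ± 0.08) and FLR1 (-0.31 ± 0.08), the last lost after cyclic loess (adjusted p = 0.155). Their median was 0.12 (camera adjusted p = 0.0578), and the list passed without control replicate 2 (adjusted p = 0.0499) or 3 (adjusted p = 0.0458), without BSA replicate 2 (adjusted p = 0.0467), with control replicates 2 and 3 as 1 sample (adjusted p = 0.0485) and with every probe set kept (adjusted p = 0.0351), in a range of 0.0351 to 0.214. Of 39 histone, cyclin and replication genes, 14 rose, HHT1 by 0.88 ± 0.06, and 17 fell, the ribonucleotide reductase genes RNR2 (-1.07 ± 0.10) and RNR4 (-0.95 ± 0.09) among them, but 16 rose and 14 fell with arrays centred on the median deviation (median -0.07, camera adjusted p = 0.755). Without control replicate 2, 9 of them rose. Of 22 purine and one-carbon genes, 9 fell, IMD3 by -0.85 ± 0.05, and 0 rose in limma, adjusted or not, but without control replicate 1, whose values set it apart here, 10 rose and 9 fell (median -0.24, camera adjusted p = 0.493). GCV1 (0.94 ± 0.47) and SHM2 (0.62 ± 0.34) did not pass with all arrays and rose by 1.56 and 1.06 without that array (adjusted p = 8.41e-05 and 0.000261), and passed with array weights (adjusted p = 7.92e-05 and 0.000146). Of 28 vitamin and NAD genes, 8 rose, BNA1 by 1.53 ± 0.06, and 6 fell, 5 adjusted over the list alone, with THI7 at -0.94 ± 0.05 (median 0.07, camera adjusted p = 0.221), and without control replicate 1, 13 rose. The other 4 lists of this paragraph kept their counts when adjusted over the list alone, and apart from RSB1, PDR5, QDR2, PDR1 and FLR1 these genes were chosen after their values were seen.

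Ribosomal protein genes fell while respiratory chain genes rose. A bias with brightness is argued against for ribosomal protein genes. Their median lay 0.668 (log2) below the outermost of 10000 lists of equally bright genes (-0.668). The respiratory median lay only 0.129 above the outermost of such lists. This fell short of the distance asked of the ribosomal list, so that comparison does not settle it. After cyclic loess the respiratory median was 0.648, which argues against this bias there too. A bias with gene length is argued against as well. The smaller of both medians was still 0.573 after the trend with length was removed. These lengths can include introns (1001 bases for RPS9B, not a whole number of codons), so a trend with coding length itself was not tested. Glucose used up in the BSA cultures alone asks that glucose-repressed genes be low without BSA and rise with it. A set of 9 glucose-repressed genes had a median of -0.0533 (SD 0.64), and 2 of them were at least 2-fold higher. Some genes of the gluconeogenesis list were already bright without BSA, with mean log2 expression of 10.88 for PCK1, 9.03 for ADH2 and 8.72 for FBP1. CAT8 was at 7.56, and the control arrays had medians of 7.61. Glucose used up in the BSA cultures alone is argued against for these 9 genes. They did not rise as a set, and some were already bright in the controls. Of 23 genes of the gluconeogenesis list, 11 rose, CAT8 and FBP1 among them, and 4 fell. A difference in growth phase between the groups therefore stays open. Slower growth with BSA could give the same pattern, stays untested because growth was not measured in the values used here, and may be confounded with a difference in growth phase.

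Sulfur assimilation and iron regulon genes rose together. The amino acid biosynthesis list did not rise as a whole: of 59 genes 18 rose and 29 fell as deposited, with a median of -0.165. General amino acid starvation still stays open, because the members spread widely around that median (SD 0.69). Binding of metals by BSA could raise iron genes and stays open as well, because 7 core genes of the zinc regulon, which include its regulator gene ZAP1 and the alcohol dehydrogenase gene ADH4, had a median of 0.558 and 3 copper uptake genes one of -0.0226 (SD 0.547). An effect of BSA itself on sulfur or iron supply is a hypothesis that the design does not part from other effects of the addition.

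Control replicates 2 and 3 differed with an SD of 0.0567 (log2), less than the 0.117 to 0.198 of the other pairs within a group. A candidate explanation is 1 RNA sample on both arrays, and an unusually close pair of cultures is the other, and no value here parts them. With both arrays counted as 1 sample 3953 genes passed, 3943 of them among the 4268.

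A gained or lost chromosome in the BSA cultures is argued against, since the chromosome furthest from all genes, XII of 16, had a median only 0.0934 (log2) lower (-0.0934). The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 4268 genes and the highest other 0 (1 of 10 splits as large), and 12 lists against 18 in the highest other (10 of 10). Each other split sets 2 arrays of one group and 1 of the other against the rest, so it still holds part of the difference between the groups.

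The members of 4 pairs of genes of related function are set side by side here. LYS20 rose by 2.71 while LYS21 changed by -0.45 (difference 3.16 ± 0.11 SE), RPS27A by 1.15 against -0.50 for RPS27B (1.65 ± 0.18), SUL2 by 3.40 against -0.40 for SUL1 (3.80 ± 0.35), and CYC7 by 4.60 against 0.49 for CYC1 (4.11 ± 0.16). SUL1 did not pass (adjusted p = 0.302), but fell by 0.76 without BSA replicate 2 (adjusted p = 0.031) and by 0.52 with array weights (adjusted p = 0.0199), and was at -0.077 without BSA replicate 1, in a range of adjusted p of 0.0199 to 0.818. The pairs were picked because their members differed, so their differences are values and not a test.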
